A study of Homo sapiens with 10 samples.

How the data were processed

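RNA from H1 human embryonic stem cells and from neural cells made from them was hybridised to Affymetrix Human Genome U133 Plus arrays. Per the labels' protocols, H1 cells were kept in mTeSR1, a defined medium for pluripotent cells, and differentiated with the STEMdiff neural differentiation system. Total RNA was purified with an RNeasy kit and labelled with biotin. Arrays fell into 5 groups of 2: rosettes and neural progenitor cells (NPC), each with 0 or 20 mM ethanol, and undifferentiated cells of passage 40. The design text calls the 2 arrays of a group biological duplicates, so each p-value of a single gene measures the spread between duplicates of one cell line. A p-value of a gene list compares the list with all other genes and rests mainly on the spread across genes. The labels give no array date, dish or batch, and the length of the ethanol exposure is not stated in them.

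The deposited table holds 1 intensity per probe set and array, made with MAS5, the Affymetrix signal algorithm, per the submitters' processing notes. The notes state no version, scaling target or filter. The scale was read from the values: 54675 probe sets per array were on a linear scale, and the 2% trimmed mean lay between 500.06 and 500.07 on all 10 arrays, so each array had been scaled to a trimmed mean of about 500. No further scaling was applied. MAS5 scaling makes the arrays' averages equal, so a change in total messenger RNA per cell could not be measured. Total signal per array lay between 42731089 and 46851098 units, and the median probe set lay between 68 and 81 units. Detection calls were not used here, so a value below the array median was treated as not distinguishable from background.

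Probe sets were named through the platform annotation, with symbols updated by gene identifier against the RefSeq gene table of GRCh38.p14. Of the 54675 probe sets, 41091 carried 1 symbol, 1801 several, 11721 none, and 62 were control probe sets. Among those with 1 symbol, 54 could not be matched by identifier and kept the platform's name. Probe sets with several symbols named no gene. For each of 19775 symbols the probe set with the highest mean over all arrays was taken. A gene was kept when at least 2 of the 10 arrays exceeded that array's median, which left 14130 genes. Where several probe sets of a kept gene existed, their directions were compared among the named genes. A probe set was called in the opposite direction for SOX2 in NPC against rosettes and for ADH5 in NPC against undifferentiated cells. Probe sets of the opposite sign that were not called were found for GRIA3 in rosettes against undifferentiated cells, for DLL3, ETS1, NANOG and OTX2 in NPC against rosettes, for ADH5, EPHA7, NES and PAX6 with ethanol in NPC, and for ADH5, CAT, PAX6 and SLC7A11 in the average. Symbols of processed pseudogenes and near-identical copies (POU5F1B, POU5F1P3, POU5F1P4, ANXA2P2, HLA-DPB2, NANOG with its retro-copies, and the metallothioneins MT1M and MT1X) are reported as uncertain between copies.

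Values were transformed to log2 of the signal plus 19.01, a pseudocount equal to the mean over arrays of the 25th percentile of the probe sets. The model was limma 3.58.1 in R 4.3.3: group means over all 10 arrays with 5 residual degrees of freedom, moderated variances with a trend on mean signal, and a prior of 6.14 degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and calls of at least 2-fold were also counted. The median standard error of a log2 fold change was 0.13, against 0.0917 for the averaged ethanol effect and 0.183 for the difference between stages. The pseudocount shrinks the fold change of dim genes. Where all arrays of the dimmer group lay below their array's median, the fold is therefore given as a bound ("at least N-fold"): the brighter group's mean log2 signal minus the dimmer group's mean of the higher of its own signal and the array median. No fold is given where that bound did not exceed 1. Where only some arrays of the dimmer group lay below their array's median, the log2 fold change holds the pseudocount and depends on it.

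The tests covered rosettes against undifferentiated cells, NPC against undifferentiated cells and NPC against rosettes, all without ethanol, then ethanol against none in rosettes and in NPC, the mean of both ethanol effects, and their difference (NPC minus rosettes). Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 23 lists of each comparison. The lists covered pluripotency, neural stem cells, forebrain, midbrain and hindbrain, neurons, glia, neural crest, mesenchyme, mesoderm and endoderm, surface ectoderm, mitosis, ethanol metabolism, oxidative stress, the unfolded protein and integrated stress response, p53 targets, cholesterol synthesis, retinoic acid, Wnt signalling, Notch signalling, glycolysis and hypoxia, DNA methylation, ion channels, and adhesion with axon guidance.

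The groups, the test, the lists, the alternatives and the rule for naming genes were set before the data were examined. That rule takes, per comparison, the 6 calls with the largest rise and the 6 with the largest fall among genes whose arrays do not overlap between groups, up to 2 called members of each list, and fixed marker genes. With fewer than 6 calls in a direction in an ethanol comparison, it takes the 3 genes with the smallest p, as values. Of the fixed markers, 8 of 10 stage markers and 7 of 7 ethanol markers had a kept probe set. List members named without a value as the few that rose or fell were chosen after their values were seen, and other genes outside the rule are marked as such. Rescaling by the hybridisation spikes, a further mesenchymal list and a list of FGF and ERK feedback genes were added after results had been seen.

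Alternative settings changed the pseudocount, the filter, the scaling between arrays (quantile normalization or centring on the array median), the choice of probe set, the variance model and the arrays in the fit, added the replicate number as a block, or left out each array in turn. When an array was left out, the remaining array of its group was assumed to vary like the other groups. The steps were also tested on simulated data. These were built from the fitted means and variances of the real arrays with independent normal noise, which is a favourable case. With ethanol effects in NPC simulated over 14130 genes, 55.2% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 97% of those changed 4-fold were called, 12 of 167 calls were false, and 0 genes were called in the unchanged rosettes. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.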

Results

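Genome-wide expression was measured in H1, an established human embryonic stem cell line, and in 2 neural stages derived from it. Neural rosettes are radial clusters of early neuroepithelial cells, and neural progenitor cells (NPC) are the expandable cells obtained from them. Each stage was made with 0 or 20 mM ethanol, and undifferentiated cells of passage 40 were the parental control, with 2 arrays in each of the 5 groups. Total signal over all probe sets lay between 42731089 and 46851098 units per array. The number of arrays limits the precision of every comparison. Across the 14130 genes tested, arrays of one group correlated at r = 0.988 to 0.990, those of one stage with and without ethanol at 0.986 to 0.989, rosettes with NPC at 0.941 to 0.950, and undifferentiated with neural arrays at 0.810 to 0.864. These correlations are across genes, which are not independent replicates. The first principal component carried 67.5% of the variance and set undifferentiated cells apart from both neural stages. The second, with 21.3%, separated rosettes from the other stages, and the third held 2.09%. On the third, neural arrays scored from 4.19 to 20.8 without ethanol and from -16.93 to -3.489 with it. The ratio of 3' to 5' ACTB signal, a sign of RNA integrity, was 1.83 ± 0.040 (SD, n = 2) in undifferentiated cells and 1.32 ± 0.012 in rosettes without ethanol. It was 1.46 ± 0.061 in rosettes with ethanol, 1.53 ± 0.14 in NPC without and 1.43 ± 0.090 in NPC with ethanol, and the GAPDH ratio lay between 0.936 and 1.06 on every array.

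The first comparison asked which transcripts change when H1 cells become rosettes. Rosettes without ethanol had far lower pluripotency transcripts and far higher early neural ones. ZIC1, a zinc-finger factor of the early neural plate, rose from 64.8 ± 5.2 to 22950 ± 1590 signal units (mean ± SD, n = 2), at least 323-fold. SOX1, among the earliest markers of committed neuroectoderm, rose at least 84.4-fold, and EMX2, a patterning factor of the dorsal forebrain, at least 80.1-fold (adjusted p = 3.16e-13, limma). SCNN1A, a subunit of the epithelial sodium channel, was at least 95.3-fold lower, and APELA, a peptide hormone secreted by embryonic stem cells, fell by 7.17 ± 0.30 on the log2 scale (± SE here and below, n = 2). NANOG, a core factor of the pluripotent state, fell by 5.18 ± 0.44.

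Of the 17 pluripotency genes measured, 0 rose and 16 fell (16 adjusted over the list alone; camera adjusted p = 1.56e-08, with 9138 of all genes at an unadjusted p under 0.05 in limma). PRDM14, a germline and pluripotency regulator, was at least 34.3-fold lower. POU5F1B, POU5F1P3 and POU5F1P4, which cannot be told from the near-identical POU5F1 on this array, were at -6.44 ± 0.20, -5.99 ± 0.16 and -6.01 ± 0.27, all called lower. Of 23 neural stem cell genes, 21 rose and 2 (SOX2 and ZIC2) fell, the same counts as adjusted over the list alone (median log2 fold change 3.94, adjusted p = 4.94e-12). PAX6, a regulator of forebrain and eye neuroepithelium, rose by 4.28 ± 0.082, and POU3F3, a cortical POU-domain factor, at least 63.8-fold. NES, an intermediate filament of neural stem cells, rose by 1.44 ± 0.091. SOX2, which is shared by pluripotent and neural stem cells, fell by only 0.30 ± 0.088 (adjusted p = 0.0111), with -0.27 (adjusted p = 0.0635) without rosette array 1 and -0.29 (adjusted p = 0.0603) without undifferentiated array 2. SOX2 was at -0.03 (adjusted p = 0.702) when arrays were scaled to the hybridisation spikes, and the adjusted p of SOX2 over all alternatives ranged from 0.000498 to 0.702.

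Forebrain genes rose in 14 of 16 cases and HESX1 fell, against 15 and 1 adjusted over the list alone (median 2.33, adjusted p = 6.54e-06). FEZF2, a factor of the rostral forebrain, was at least 31.2-fold higher. OTX2, which acts in both epiblast and forebrain, rose by 0.19 ± 0.065 (adjusted p = 0.0248). This call ended without rosette array 2 (adjusted p = 0.126) and without undifferentiated array 1 or 2 (0.118 and 0.0618), and the adjusted p of OTX2 over all alternatives ranged from 0.000508 to 0.149. Of 19 Notch signalling genes, 15 rose and HEY2 fell, with the same counts adjusted over the list alone (adjusted p = 1.96e-06). The Notch effectors HES5 and HES4 rose by 6.03 ± 0.069 and 5.70 ± 0.15. Neuronal genes rose in 15 of 21 cases and 3 (GAP43, RBFOX3 and NEFM) fell, also adjusted over the list alone (median 1.69, adjusted p = 0.00134). STMN2, a microtubule regulator of growing neurites, rose by 4.86 ± 0.12, and DCX, which marks migrating young neurons, by 2.71 ± 0.081. All 14 cholesterol synthesis genes rose, also adjusted over the list alone (median 1.18, adjusted p = 1.96e-06). Among them INSIG1, a sterol sensor of that pathway, rose by 2.95 ± 0.078 and STARD4, a sterol carrier, by 2.53 ± 0.075.

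Mesenchymal genes rose in 15 of 18 cases and THY1 fell, as they did adjusted over the list alone (median 2.03, adjusted p = 3.69e-07). The collagen COL3A1 was at least 26.7-fold and the proteoglycan LUM at least 20.3-fold higher. COL8A1, a collagen of basement membranes, was at least 71.5-fold higher, and ZEB1, a repressor of epithelial genes, at least 83.3-fold. Adhesion and axon guidance genes rose in 19 of 25 cases and 4 fell, again also adjusted over the list alone (adjusted p = 5.70e-05); the protocadherin PCDH19 was at least 57.7-fold higher. Of 16 Wnt signalling genes, 11 rose and 5 fell (AXIN2, SP5, DKK1, SFRP1 and WNT5A), also adjusted over the list alone (adjusted p = 0.00859, and adjusted p = 0.177 with an estimated correlation). The stem cell receptor LGR5 was at least 20.6-fold higher. Surface ectoderm genes fell in 6 of 12 cases and 1 rose, the same adjusted over the list alone (adjusted p = 0.00616, and adjusted p = 0.177 with an estimated correlation). EPCAM, an epithelial adhesion molecule, fell by 3.99 ± 0.12, and the splicing regulator ESRP1 fell by 5.14 ± 0.18. Of 19 glycolysis and hypoxia genes, 6 rose and 11 fell, against 12 lower adjusted over the list alone (median -0.57, adjusted p = 0.0427, and adjusted p = 0.177 with an estimated correlation). ADM, a vasoactive peptide induced by low oxygen, fell by 3.04 ± 0.13.

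Several further lists did not shift as sets. Neural crest genes rose in 9 and fell in 4 of 15 cases (10 and 4 adjusted over the list alone; camera adjusted p = 0.11), SNAI2 being at least 8.18-fold higher. Glial genes rose in 6 of 14 cases and 2 fell, also adjusted over the list alone (adjusted p = 0.139); TNC, an extracellular matrix protein of radial glia, rose by 4.08 ± 0.15. Of 6 midbrain and hindbrain genes, 3 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.194), with FGF8, the signal of the midbrain border and the rostral forebrain, at least 14.0-fold higher. Ion channel genes rose in 8 of 13 cases and 1 fell, also adjusted over the list alone (adjusted p = 0.0841). Of 16 DNA methylation and chromatin genes, 5 rose and 8 fell, against 6 and 8 adjusted over the list alone (adjusted p = 0.458); the de novo methyltransferase DNMT3B fell by 3.32 ± 0.069, and TET2, which oxidises methylcytosine, rose by 1.80 ± 0.17. Ethanol metabolism genes rose in 3 and fell in 3 of 11 cases, also adjusted over the list alone (adjusted p = 0.934). For 3 lists the median and the mean log2 fold change differed in sign, and the test pointed down for each without passing. These were mitosis (median 0.00765, mean -0.0388, adjusted p = 0.694), the stress response list (-0.20 and 0.13, adjusted p = 0.73), where ATF3 rose by 2.35 ± 0.10, and retinoic acid genes (0.28 and -0.49, adjusted p = 0.963), where CYP26A1, which degrades retinoic acid, was at least 28.5-fold lower.

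In all, 8649 of 14130 genes (61.2%) were called, 4639 higher and 4010 lower, of which 2127 and 1207 changed at least 2-fold. Of the 23 lists, 11 passed, and 8 of these passed with an estimated correlation. Scaling to the hybridisation spikes, chosen after seeing the data, brought the median log2 fold change of all genes from 0.0217 to 0.27 and gave 6179 higher and 2426 lower calls. Medians of the surface ectoderm and the glycolysis list were then -0.20 and -0.30, against -0.46 and -0.57. The ACTB 3' to 5' ratio was lower in rosettes by -0.47 log2 units.

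NPC without ethanol were compared with undifferentiated cells to ask how the progenitors differ from their parental line. Pluripotency and epithelial transcripts were lower, and neural stem cell, neuronal and forebrain transcripts were higher. DLX1 and DLX2, homeobox factors of ventral forebrain progenitors and interneurons, were at least 121-fold and 127-fold higher, DLX2 going from 6.52 ± 0.56 to 8992 ± 459 signal units (SD, n = 2). GNRH1, the gonadotropin-releasing hormone gene, was at least 110-fold higher (adjusted p = 1.70e-11, limma). ZIC1 was at least 404-fold, POU3F3 at least 133-fold and NR2E1, which maintains neural stem cells, at least 73.2-fold higher. APELA was at least 203-fold and SCNN1A at least 92.0-fold lower, and the adhesion molecule CDH1 fell by 7.21 ± 0.18.

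Of 17 pluripotency genes, 0 rose and 16 fell, also adjusted over the list alone (median -2.67, camera adjusted p = 1.08e-08, 9730 of all genes having an unadjusted p under 0.05 in limma). NANOG was at least 47.7-fold and PRDM14 at least 33.1-fold lower. Neural stem cell genes rose in 21 of 23 cases and 1 fell, also adjusted over the list alone (median 4.88, adjusted p = 2.62e-11), including SOX1 (at least 95.3-fold) and PAX6 (4.88 ± 0.082). Neuronal genes rose in 20 of 21 cases and RBFOX3 fell, again the same adjusted over the list alone (median 4.07, adjusted p = 2.97e-10); STMN4 was at least 104-fold higher, STMN2 rose by 7.01 ± 0.12 and DCX by 4.49 ± 0.081. Forebrain genes rose in 12 of 16 cases and 1 fell, against 13 and 1 adjusted over the list alone (adjusted p = 1.77e-05). OTX2 was at 0.16 ± 0.065 and did not pass (adjusted p = 0.0501). SOX2 fell by 0.38 ± 0.088 (adjusted p = 0.00234), against -0.01 (adjusted p = 0.881) under spike scaling, over a range of 0.000278 to 0.881 for its adjusted p.

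Adhesion and axon guidance genes rose in 21 of 25 cases and 2 fell, also adjusted over the list alone (adjusted p = 1.39e-07), with the ephrin receptor EPHA3 at least 29.4-fold higher. Ion channel genes rose in 9 of 13 cases and 3 fell, also adjusted over the list alone (adjusted p = 0.0179, and adjusted p = 0.0771 with an estimated correlation). The sodium channel gene SCN3A was at least 18.9-fold higher, and the glutamate receptor gene GRIA2 at least 12.2-fold. Notch signalling genes rose in 15 of 19 cases and 1 fell, also adjusted over the list alone (adjusted p = 5.86e-06), and 13 of 14 cholesterol synthesis genes rose with 0 falling, also adjusted over the list alone (adjusted p = 2.25e-06). Mesenchymal genes rose in 13 of 18 cases and 3 (THY1, MYL9 and CNN1) fell, the same adjusted over the list alone (adjusted p = 0.00179), with LUM at least 34.7-fold higher.

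All 12 surface ectoderm genes fell, also adjusted over the list alone (median -3.13, adjusted p = 2.60e-07), ESRP1 being at least 75.3-fold lower. Oxidative stress genes fell in 9 of 16 cases and 0 rose, also adjusted over the list alone (median -0.43, adjusted p = 0.000617), and their median was -0.0595 under spike scaling. The metallothionein MT2A, which binds zinc and copper, fell by 4.37 ± 0.13, and MT1X, uncertain among related copies, fell by 4.25 ± 0.096. Mitotic genes fell in 12 of 20 cases and 3 rose (4 adjusted over the list alone; median -0.31, adjusted p = 0.0122, and adjusted p = 0.0623 with an estimated correlation), and their median was 0.0547 under spike scaling. The checkpoint kinase BUB1 fell by 1.49 ± 0.061. Glycolysis and hypoxia genes fell in 12 of 19 cases and 6 rose, also adjusted over the list alone (median -0.96, or -0.59 under spike scaling, adjusted p = 0.0205, and adjusted p = 0.143 with an estimated correlation). The mesoderm and endoderm list did not shift, with 2 of 10 genes higher and 1 lower, against 1 and 1 adjusted over the list alone (adjusted p = 0.81). Its member EOMES, also a factor of cortical intermediate progenitors, rose by 5.09 ± 0.091.

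A total of 9389 genes (66.4%) were called, 4847 higher and 4542 lower, with 2493 and 1669 changed at least 2-fold, and 13 lists passed, 10 of them with an estimated correlation. Spike scaling brought the median of all genes from 0.0178 to 0.36 and gave 6910 higher and 2615 lower calls, and the ACTB 3' to 5' ratio was lower in NPC by -0.26 log2 units.

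**Figure D1:**
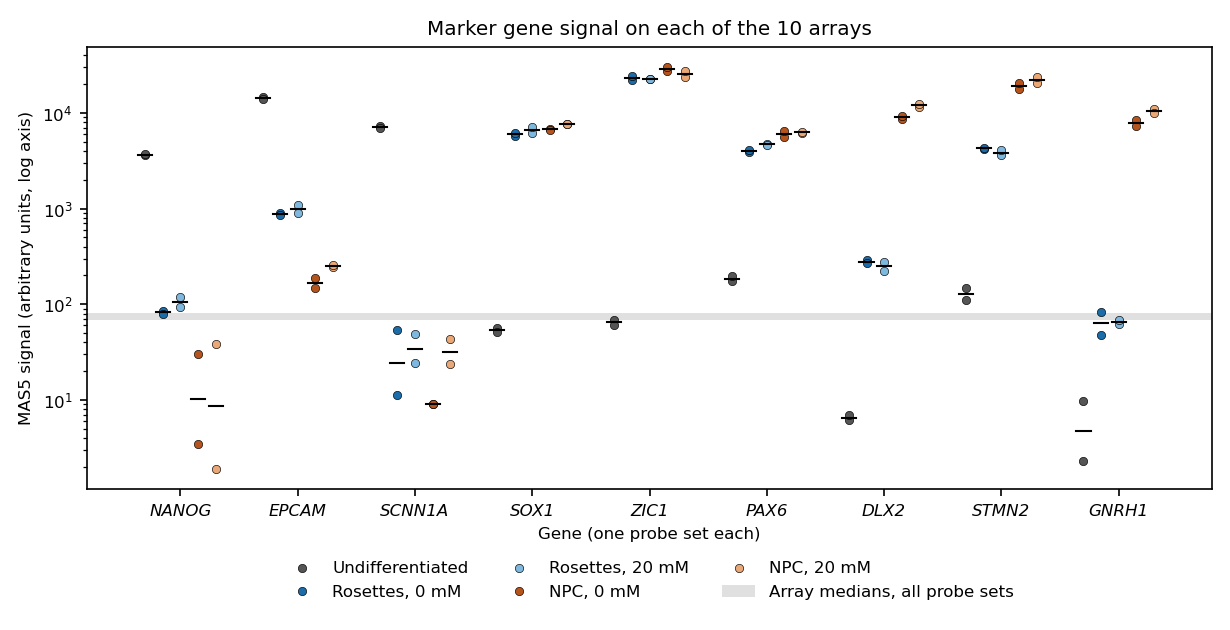
MAS5 signal (arbitrary units, log axis) of 9 marker genes on each of the 10 arrays, with bars at the geometric mean of the 2 arrays of a group and a grey band from 68 to 81 units, the range of array medians. NANOG, EPCAM and SCNN1A were highest in undifferentiated cells, ZIC1, SOX1 and PAX6 were high in both neural stages, and DLX2, STMN2 and GNRH1 were highest in NPC.

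Both neural stages shared most of their calls against undifferentiated cells: 3852 genes were higher in both and 3385 lower in both, while 200 moved in opposite directions. Independent lists would share 1591 and 1289. The stages were compared with the same 2 control arrays, and in 20 simulated runs with unchanged groups against these controls a median of 0 calls was shared. No gene changed in these runs, so that count cannot show how many shared calls the controls add among changed genes. Fold changes of both stages correlated at r = 0.865 across genes (covariance 1.27), against 0.503 (covariance 0.0215) in the simulated runs. The 2 controls were not split between the stages, so some shared calls may come from them. The simulated covariance of 0.0215 was small beside 1.27, which argues against spread between the control arrays as the source of most of the covariance.

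NPC were next compared with rosettes, both without ethanol, to ask how the 2 neural stages differ. NPC had higher neuronal transcripts and lower epithelial, mitotic and mesenchymal ones. GNRH1 rose from 65.9 ± 25 to 7837 ± 718 signal units (SD, n = 2, with adjusted p = 1.08e-09 in limma). Of the rosette arrays only array 1 lay below its median (48.22 against 73.03 units), so a fold would depend on the pseudocount and is not given. DLX2 rose by 4.92 ± 0.11, and BCL11A, a zinc-finger factor of cortical neurons, by 5.13 ± 0.13, its level in undifferentiated cells (4042 ± 93.5 units) being near that in NPC (3393 ± 0.90). EGR1 and FOS, immediate-early genes of growth factor signalling, fell by 5.07 ± 0.072 and at least 11.2-fold. SPP1, a secreted matrix phosphoprotein, fell by 4.50 ± 0.083, and GREM1, an antagonist of bone morphogenetic proteins, by 4.36 ± 0.090.

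Neuronal genes rose in 19 of 21 cases and RBFOX3 fell, also adjusted over the list alone (median 2.34, camera adjusted p = 3.98e-17). ISL1, a factor of motor and ventral forebrain neurons, rose by 4.27 ± 0.15, and MYT1L, a neuronal identity factor, at least 6.11-fold. Of 13 ion channel genes, 5 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.00856, and adjusted p = 0.0682 with an estimated correlation), among them GRIA2, at least 11.7-fold higher. Adhesion and axon guidance genes rose in 13 of 25 cases and 3 fell (4 adjusted over the list alone; adjusted p = 0.000125); CNTN1, a neuronal adhesion molecule, rose by 3.77 ± 0.22 and SLIT1, an axon repellent, by 2.62 ± 0.14. Neural stem cell genes rose in 11 of 23 cases and 5 fell, also adjusted over the list alone (adjusted p = 0.0189, and adjusted p = 0.227 with an estimated correlation). POU3F2 rose by 2.77 ± 0.15 and PAX6 by 0.60 ± 0.082, while SOX1 was at 0.17 ± 0.079 (adjusted p = 0.11), SOX2 at -0.08 ± 0.088 (0.511) and OTX2 at -0.03 ± 0.065 (0.746). Forebrain genes rose in 6 of 16 cases and 1 fell, also adjusted over the list alone (median 0.16, adjusted p = 0.0384, and adjusted p = 0.115 with an estimated correlation). That call ended without NPC array 1 of the group without ethanol (adjusted p = 0.0624) and without either NPC ethanol array (0.0555 and 0.0537).

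All 12 surface ectoderm genes fell, also adjusted over the list alone (median -2.45, adjusted p = 1.53e-10); CDH1 fell by 3.95 ± 0.18 and the keratin KRT18 by 3.08 ± 0.070. Mesenchymal genes fell in 10 of 18 cases and COL3A1, LUM and DCN rose (4 adjusted over the list alone; median -0.96, adjusted p = 0.00103). Those that fell included the actin-binding proteins CNN1 (-2.88 ± 0.11) and TAGLN (-2.87 ± 0.077). Mitotic genes fell in 14 of 20 cases and 0 rose, against 15 lower adjusted over the list alone (median -0.30, adjusted p = 1.34e-05), with the kinase AURKA down by -0.67 ± 0.061. Of 17 pluripotency genes 8 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.00103, and adjusted p = 0.0555 with an estimated correlation); LIN28A, an RNA-binding protein of early cells, fell by 2.15 ± 0.082. Oxidative stress genes fell in 9 of 16 cases and 0 rose, also adjusted over the list alone (adjusted p = 0.00103), NQO1 by -1.43 ± 0.097. The p53 list fell in 9 of 14 cases and 2 rose, also adjusted over the list alone (adjusted p = 0.0071, and adjusted p = 0.0676 with an estimated correlation); GADD45A, a stress-induced growth arrest gene, fell by 1.58 ± 0.11. Neural crest genes fell in 8 of 15 cases and 2 rose, also adjusted over the list alone (adjusted p = 0.0298, and adjusted p = 0.109 with an estimated correlation). Glycolysis and hypoxia genes fell in 10 of 19 cases and 3 rose (4 adjusted over the list alone; adjusted p = 0.0389, and adjusted p = 0.2 with an estimated correlation); this call ended without rosette array 1 (adjusted p = 0.0573) or NPC array 1 (0.0552), both of the groups without ethanol. The neuronal glucose transporter SLC2A3 fell by 2.91 ± 0.064.

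The median and the mean differed in sign for glial (0.15 and -0.12), retinoic acid (-0.25 and 0.12) and chromatin genes (-0.00919 and 0.0826), and for mesoderm genes both were negative (-0.53 and -0.0953) while the test pointed up; none of the 4 lists passed. A total of 5050 genes (35.7%) were called, 2348 higher and 2702 lower, 631 and 623 of them at least 2-fold, with 6365 at an unadjusted p under 0.05. Under spike scaling the calls split 3145 higher to 1877 lower, and the medians of the mitotic, oxidative stress and glycolysis lists were -0.195, -0.181 and -0.198, against -0.296, -0.271 and -0.300; the forebrain median was then 0.256. Of 13 lists that passed, 6 did so with an estimated correlation. The ACTB 3' to 5' ratio was higher in NPC by 0.22 log2 units.

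The effect of 20 mM ethanol was asked in each stage separately. In rosettes, every gene that passed was lower with ethanol, and mesenchymal genes were lower as a set. TAC1, which encodes the neuropeptide substance P, fell from 966 ± 93 to 345.0 ± 9.4 signal units (SD, n = 2), a log2 change of -1.43 ± 0.099 (adjusted p = 0.000207, limma). SPP1 fell by 0.88 ± 0.083 (adjusted p = 0.00282), LUM by 1.00 ± 0.14 (0.0214) and LOX, which cross-links collagen and elastin, by 0.94 ± 0.14 (0.0336). CYP1B1, an oxidase of steroids and retinoids, fell by 1.15 ± 0.17 (0.0291), and the cadherin CDH6 by 0.67 ± 0.076 (0.00848). ANXA2P2, which cannot be told from the related ANXA2 transcript, fell by 1.63 ± 0.19 (0.00848). These 7 genes were part of 14 calls, all lower, of which ANXA2P2, TAC1 and CYP1B1 changed at least 2-fold.

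No gene was called higher (0 calls in limma), and 1200 genes of either direction had an unadjusted p under 0.05. The 3 rises with the smallest p did not pass: QPCT was at 0.49 ± 0.088 and C3orf18 at 0.70 ± 0.13 (adjusted p = 0.0874 for both), and PPFIA3 was at 1.29 ± 0.25 (0.132). Genes of ethanol handling did not pass either, with ADH5 at 0.05 ± 0.087, ALDH2 at 0.06 ± 0.10, CAT at 0.02 ± 0.085 and the stress enzyme HMOX1 at 0.37 ± 0.26. The neural markers PAX6 (0.24 ± 0.082), SOX1 (0.15 ± 0.079) and NES (-0.12 ± 0.091) did not pass, and adjusted p for these 7 fixed markers lay between 0.434 and 0.977.

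Mesenchymal genes shifted down as a set with ethanol in rosettes (median -0.35, camera adjusted p = 1.39e-08). Over all genes 0 rose and 1 fell, against 1 and 9 of 18 adjusted over the list alone. In these same arrays the ACTB 3' to 5' ratio was higher with ethanol by 0.15 log2 units. The 18 genes of the unfolded protein and integrated stress response shifted down (median -0.14, adjusted p = 7.29e-06, and adjusted p = 0.0608 with an estimated correlation), as did p53 targets (14 genes, median -0.15, adjusted p = 0.00129, and adjusted p = 0.0608 with an estimated correlation). Of these, 0 genes passed over all genes, and 3 and 2 fell adjusted over the list alone. Neural crest genes (median -0.24, adjusted p = 0.0016, and adjusted p = 0.0608 with an estimated correlation) had 3 of 15 lower adjusted over the list alone. The 16 oxidative stress genes (median -0.0908, adjusted p = 0.00213, and adjusted p = 0.0608 with an estimated correlation) also had 3 lower adjusted over the list alone, and their call ended without rosette array 2 of the group without ethanol (adjusted p = 0.0915). Under centring on the array median, the medians were closer to 0: -0.265 for mesenchyme, -0.0611 for the stress response, -0.0632 for p53 targets, -0.162 for neural crest and -0.00894 for oxidative stress.

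Shifts were also called for mitotic genes (median 0.0487, adjusted p = 0.0485), glial genes (median -0.15, adjusted p = 0.049) and adhesion genes (median -0.03, adjusted p = 0.049; CDH6 fell). With an estimated correlation these gave adjusted p = 0.148, 0.191 and 0.148. The mitotic call ended without any of the 4 rosette arrays or either undifferentiated array (adjusted p from 0.0546 to 0.161). The glial call ended without any rosette array, either undifferentiated array or NPC ethanol array 2 (0.0502 to 0.248). The adhesion call ended without any one of the 10 arrays (0.0521 to 0.204), and the median of that list was 0.0519 under centring on the array median, against 0.131 for the mitotic and -0.0631 for the glial list. Under spike scaling the mitotic median was 0.00691. Adjusted over the list alone, 0 mitotic, 0 glial and 2 adhesion genes passed. The glycolysis list did not shift in rosettes (median -0.04, adjusted p = 0.161; 2 genes lower adjusted over the list alone).

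The number of calls in rosettes was 1 without any one of the 4 rosette arrays, and TAC1 alone among the 7 named genes passed in each of these fits, the other 6 having an adjusted p between 0.0568 and 0.3. LOX and CYP1B1 also missed the threshold without either NPC ethanol array (0.0568 and 0.0574). Centring on the array median, which brought the median of all genes from 0.00627 to 0.0881, left 4 calls and 7 lists. Without that centring 8 lists passed, 1 of them with an estimated correlation. With the mean of a gene's probe sets SPP1, LUM, LOX, CYP1B1 and CDH6 missed the threshold (0.155 to 0.336), and without a variance trend all 6 genes other than TAC1 did (0.0564 to 0.139). With a pseudocount of 1 LUM and LOX missed it (limma adjusted p = 0.544 and 0.0795). So did LOX and CYP1B1 without the filter on low values (0.085 and 0.0807), and LOX with the replicate block (0.0656).

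In NPC with ethanol, glycolysis and hypoxia genes were higher as a set, and single genes were called in both directions. VEGFA, the main angiogenic growth factor induced by low oxygen, rose from 1686 ± 60 to 3697 ± 123 signal units (SD, n = 2), a log2 change of 1.12 ± 0.079 (adjusted p = 6.33e-05, limma). ETV5, a transcription factor downstream of fibroblast growth factors, fell from 2353 ± 177 to 936.5 ± 104 units (-1.31 ± 0.092, adjusted p = 6.33e-05), and the related ETV4 was at least 2.68-fold lower (0.00573). LGI1, a secreted synaptic protein, fell by 1.45 ± 0.13 (0.00032), WNT7B, a Wnt ligand of the forebrain, by 1.49 ± 0.16 (0.00114), and LUM by 1.40 ± 0.14 (0.000507).

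Of the 19 glycolysis and hypoxia genes, 13 rose and 0 fell, against 16 and 1 adjusted over the list alone (median 0.41, camera adjusted p = 1.05e-25, and adjusted p = 0.00546 with an estimated correlation). EGLN3, an oxygen-sensing prolyl hydroxylase, was at least 1.81-fold higher (adjusted p = 0.0241). Members chosen after their values were seen were PDK1, which limits entry of pyruvate into mitochondria (0.98), BNIP3, a mitophagy receptor (0.98), LDHA, which makes lactate (0.89), and the glucose transporter SLC2A1, which was at -0.29 and fell when adjusted over the list alone. This was the one list of 23 to pass in NPC.

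**Figure D2:**
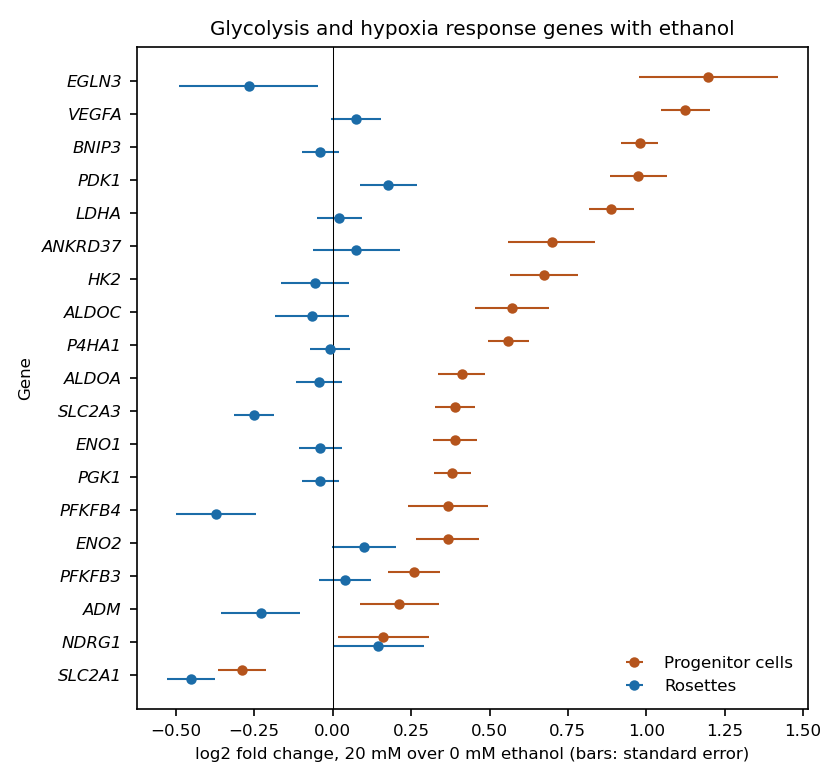
Log2 fold change (20 over 0 mM ethanol) of the 19 measured genes of the glycolysis and hypoxia list, in NPC (orange) and rosettes (blue), with bars of 1 standard error. In NPC 18 members lie above 0 and SLC2A1 lies at -0.29, and the list median was 0.41 in NPC and -0.04 in rosettes.

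TFAP2C, a factor of neural crest and early ectoderm, fell by 0.96 ± 0.099 (adjusted p = 0.000691), EOMES by 0.81 ± 0.091 (0.00131) and FEZF2 by 0.79 ± 0.11 (0.00404). EMX2 fell by 0.50 ± 0.090 (0.0217), and the axon repellent SLIT2 by 0.73 ± 0.11 (0.00983). Forebrain genes did not shift as a set (0 higher and FEZF2, EMX2 and OTX2 lower, against 4 and 3 adjusted over the list alone; adjusted p = 0.857). Of 16 Wnt signalling genes 2 rose and 2 fell, against 4 and 6 adjusted over the list alone (camera adjusted p = 0.484). SFRP1 and FZD5 rose, and those that fell were LGR5 (-1.04 ± 0.20) and RSPO1, which amplifies Wnt signals (-0.80 ± 0.14). With a pseudocount of 1 LGR5 missed the threshold (limma adjusted p = 0.616). Without a variance trend both LGR5 and RSPO1 did (0.12 and 0.0721). Of 19 Notch genes, 1 rose and 1 fell, against 2 and 8 adjusted over the list alone (adjusted p = 0.16): the effector HEY1 rose by 0.82 ± 0.098 and the ligand JAG1 fell by 0.37 ± 0.059. The receptor genes CHRNA3, a nicotinic acetylcholine receptor subunit, and DRD4, a dopamine receptor, fell by 0.91 ± 0.13 and at least 2.06-fold.

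Genes that rose outside the hypoxia list included DDIT4, a stress-induced inhibitor of mTOR (0.80 ± 0.080), SLC1A3, a glial glutamate transporter (0.63 ± 0.10), SFRP4, a secreted Wnt antagonist (1.42 ± 0.20), and BHLHE40, a repressor linked to the circadian clock and hypoxia, at least 2.28-fold. With the mean of its probe sets BHLHE40 was at 0.29 and did not pass (adjusted p = 0.768). The largest log2 rises belonged to dim genes. SPTBN4, a spectrin of axon initial segments, was at least 1.92-fold higher, TYRP1, an enzyme of pigment synthesis, at least 1.18-fold and C5orf46 at least 1.17-fold. AP1M2 and VRTN rose (adjusted p = 0.00959 and 0.0493) at levels near background and are given no fold, and the VRTN call ended without any one of the 10 arrays (0.0516 to 0.275). Of the mesenchymal list 1 rose and 2 (LUM and FBN1) fell, against 3 and 7 adjusted over the list alone (median -0.20, adjusted p = 0.119); TAGLN rose by 0.53 ± 0.077. Of 17 pluripotency genes 2 rose and LIN28B fell, against 2 and 2 adjusted over the list alone (adjusted p = 0.365), ZFP42 by 0.81 ± 0.12 from 98.1 units. The ethanol metabolism list had 0 calls over all genes or adjusted over the list alone (adjusted p = 0.923; 1690 of all genes had an unadjusted p under 0.05 in limma). ADH5 (-0.05 ± 0.087), ALDH2 (-0.02 ± 0.10), CAT (-0.03 ± 0.085), HMOX1 (-0.36 ± 0.26), NES (-0.02 ± 0.091), PAX6 (0.05 ± 0.082) and SOX1 (0.17 ± 0.079) did not pass (adjusted p from 0.415 to 0.975).

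In NPC 203 genes (1.44%) were called, 107 higher and 96 lower, 19 and 13 of them at least 2-fold. The count was 129 and 128 without rosette ethanol array 1 or 2, 99 and 105 without NPC array 1 or 2 of the group without ethanol, and 98 and 65 without NPC ethanol array 1 or 2. Calls split 129 higher to 40 lower under centring on the array median and 75 to 105 under spike scaling. The named calls that held without any one array were ETV4, ETV5, WNT7B, LGI1, LUM, TFAP2C, CHRNA3, EOMES, FEZF2, HEY1, DDIT4 and VEGFA, and 19 others did not. Of these 12, TFAP2C, CHRNA3 and FEZF2 missed the threshold with the mean of a gene's probe sets (adjusted p = 0.187, 0.0937 and 0.0794) and LUM with a pseudocount of 1 (0.147). SLC1A3 and JAG1 also missed it with the mean of probe sets (0.247 and 0.412). The ACTB 3' to 5' ratio was lower with ethanol by -0.0940 log2 units.

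Averaged over both stages, mesenchymal genes were lower and glycolysis and hypoxia genes higher with ethanol. Such an average need not be common to both stages. The glycolysis list median was 0.411 in NPC and -0.04 in rosettes, against -0.202 and -0.347 for mesenchyme. VEGFA was at 1.12 in NPC and 0.0737 in rosettes, and DDIT4 at 0.797 and 0.101. In the average LUM fell by 1.20 ± 0.097 (adjusted p = 0.00107, limma, 4 arrays against 4), and DCN, a related small proteoglycan, by 0.89 ± 0.17 (0.0413). CDH6 fell by 0.50 ± 0.053 (0.00245), DMRT3, a factor of spinal and forebrain progenitors, by 0.91 ± 0.12 (0.00749), and A2M, a protease inhibitor, by 0.78 ± 0.13 (0.0182). PDK1 rose by 0.58 ± 0.064 and IGFBP3, a binding protein of insulin-like growth factors, by 0.59 ± 0.065 (0.00287 for both), and VEGFA by 0.60 ± 0.056 (0.00117). CSPG5, a proteoglycan of the developing brain, rose by 0.59 ± 0.076, HEY1 by 0.51 ± 0.069 and DDIT4 by 0.45 ± 0.057. HLA-DPB2, a pseudogene close to a class II histocompatibility gene, rose by 0.80 ± 0.13 (0.0167).

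Glycolysis and hypoxia genes shifted up in the average (LDHA, PDK1, VEGFA, BNIP3 and P4HA1 rose and SLC2A1 fell, against 14 and 1 adjusted over the list alone; median 0.23, camera adjusted p = 6.00e-14, and adjusted p = 0.0234 with an estimated correlation). Mesenchymal genes shifted down (0 rose and COL3A1, LUM, DCN and TGFBI fell, against 2 and 9 adjusted over the list alone; median -0.18, adjusted p = 1.48e-05, and adjusted p = 0.0386 with an estimated correlation). Neural crest genes shifted down (1 fell, 5 adjusted over the list alone; adjusted p = 0.000294, and adjusted p = 0.054 with an estimated correlation). So did oxidative stress genes (2 fell, 3 adjusted over the list alone; adjusted p = 0.00152, and adjusted p = 0.0648 with an estimated correlation), where NQO1, a quinone reductase, fell by 0.40 ± 0.069 and SLC7A11, a cystine transporter, by 0.46 ± 0.079. The stress response list also passed (median -0.0824, adjusted p = 0.0208, and adjusted p = 0.203 with an estimated correlation), with 1 gene higher, and 1 higher and 2 lower adjusted over the list alone. Its call ended without rosette ethanol array 2, NPC array 2 of the group without ethanol, or NPC ethanol array 1 (adjusted p from 0.0657 to 0.117). Under centring on the array median, the averaged medians were -0.0951 for mesenchyme, -0.156 for neural crest, -0.0331 for oxidative stress and -0.00218 for the stress response, against -0.175, -0.236, -0.113 and -0.0824 without it.

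The average gave 98 calls, 38 higher and 60 lower. It gave 45 and 41 without rosette array 1 or 2 and 45 without NPC array 1 of the groups without ethanol, 21 and 34 without rosette ethanol array 1 or 2, and 42 and 54 without NPC ethanol array 1 or 2. The split was 57 higher to 23 lower under centring on the array median and 24 to 88 under spike scaling. Of the 26 named calls, CDH6, DDIT4, DMRT3, IGFBP3, LUM, PDK1 and VEGFA held without any one array, and each of these 7 ended under another alternative. With the mean of a gene's probe sets DMRT3, PDK1, VEGFA and CDH6 missed the threshold (adjusted p = 0.441, 0.422, 0.1 and 0.1), as LUM did with a pseudocount of 1 (0.105), and DDIT4 and IGFBP3 without a variance trend (0.0689 and 0.0535).

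Finally, the ethanol effects of both stages were tested against each other. TAC1 was lower with ethanol in rosettes and higher in NPC, a difference of 2.24 ± 0.14 (NPC minus rosettes, adjusted p = 7.17e-05, limma). BNIP3 (1.02 ± 0.083, 0.000248), VEGFA (1.05 ± 0.11, 0.00172) and EDN1, the vasoconstrictor endothelin (1.77 ± 0.22, 0.00469), had higher ethanol effects in NPC. ETV5 (-1.23 ± 0.13, 0.00172), EMX2OS, the antisense transcript of EMX2 (-1.10 ± 0.13, 0.00289), WNT7B (-1.54 ± 0.23, 0.0152) and LGI1 (-1.31 ± 0.19, 0.0115) had lower ones. Other genes with a higher effect in NPC were BHLHE40, DDIT4, SLC1A3, TAGLN, ZFP42 and the neuronal adhesion molecule L1CAM (0.71 ± 0.11), and TFAP2C, EOMES and RIPPLY3 had a lower one. GALNT9 and HSD11B2, dim genes near background, passed with all arrays (adjusted p = 0.0449 and 0.0446) but in 0 of the 10 fits that left 1 array out (0.0653 to 0.202 for GALNT9 and 0.0624 to 0.168 for HSD11B2).

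The glycolysis and hypoxia list had a higher ethanol effect in NPC than in rosettes (6 genes higher and 0 lower, against 15 and 0 adjusted over the list alone; median 0.62, camera adjusted p = 8.08e-27, and adjusted p = 0.00493 with an estimated correlation). The stress response list (median 0.16, adjusted p = 0.000488) and the adhesion list (median 0.19, adjusted p = 0.00449) also passed, each with adjusted p = 0.114 with an estimated correlation; each had 1 gene higher, against 3 higher and 2 higher with 1 lower adjusted over the list alone. Mitotic genes passed at a median of -0.0815 (adjusted p = 0.039, and adjusted p = 0.172 with an estimated correlation), with 0 members called over all genes (1214 genes had an unadjusted p under 0.05 in limma). That call ended without any rosette array, NPC array 2 of the group without ethanol, or NPC ethanol array 2 (adjusted p from 0.0543 to 0.215). In all, 71 genes differed, 52 with a higher and 19 with a lower effect in NPC, and the count was 25 and 30 without rosette array 1 or 2 and 42 without NPC array 2 of the groups without ethanol, 30 and 28 without rosette ethanol array 1 or 2, and 35 and 38 without NPC ethanol array 1 or 2. The named genes that passed without any one array were BNIP3, EDN1, EMX2OS, ETV5, TAC1, VEGFA and ZFP42. Of these, ETV5, ZFP42, EMX2OS and EDN1 missed the threshold with the mean of a gene's probe sets (adjusted p = 0.223, 0.0851, 0.0759 and 0.0591), as did BHLHE40, L1CAM, TFAP2C, SLC1A3 and WNT7B (0.143 to 0.629), while BNIP3, TAC1 and VEGFA passed under every alternative.

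Across the 14130 genes, ethanol effects of both stages correlated at r = 0.0305 (Spearman's rho 0.0798), with the same sign in 54.3%. These are correlations across genes, which are not independent replicates. The median standard error of an effect was 0.13 in each stage, and such noise weakens a correlation. The low r alone therefore does not show that the stages respond differently. Of 14 calls in rosettes and 203 in NPC, 6 were shared, against 0.201 for independent lists. Both comparisons use the same estimate of each gene's spread, so their calls are not independent and 0.201 may be too low a baseline. LUM fell in both stages, while GREM1, MAMDC2, NTM, SPP1 and TAC1 fell in rosettes and rose in NPC. Of the 203 NPC calls 110 had the same sign in rosettes, and of the 14 rosette calls 5 had the same sign in NPC.

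**Figure D3:**
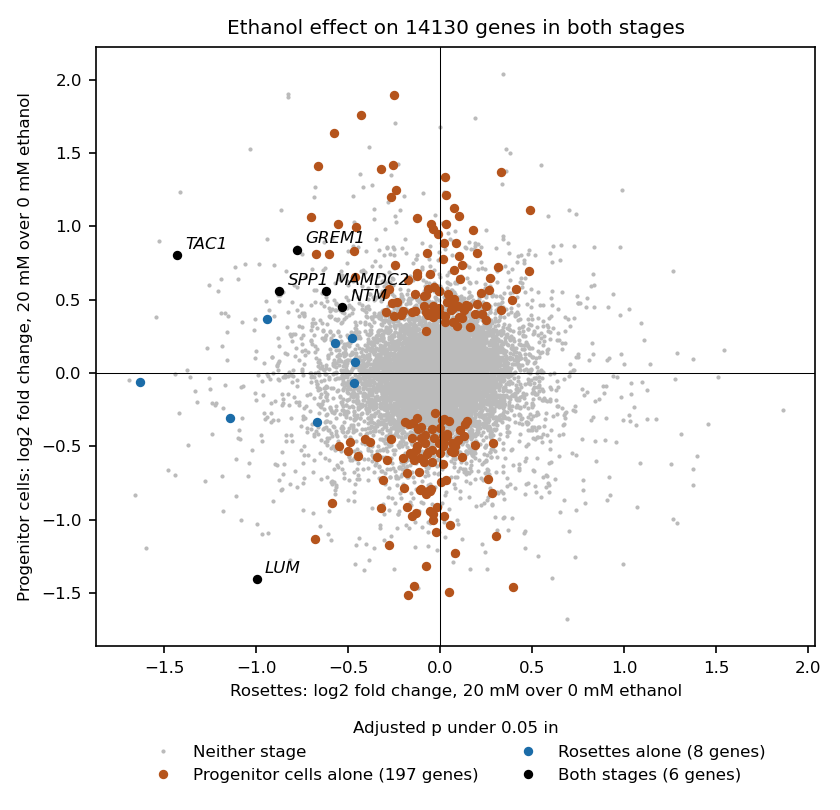
Log2 fold change (20 over 0 mM ethanol) of 14130 genes in rosettes (horizontal axis) and NPC (vertical axis). Orange points are the 197 genes called in NPC alone, blue points the 8 called in rosettes alone and black points the 6 called in both stages, of which LUM lies below 0 on both axes and the other 5 in the upper left.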

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

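Of the tests in this part, the comparison of the glycolysis list with its value in rosettes, as a sign of a culture difference, was chosen only after the result was seen. Results are listed here because the ethanol effect in NPC differed from that in rosettes by a test of the difference itself, which 71 genes and 4 gene lists passed.

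The glycolysis and hypoxia list rose with ethanol in NPC, and its median ethanol effect was 0.623 log2 units higher there than in rosettes. A single array is argued against, since the list's median stayed at 0.396 or more when any 1 of the 4 NPC arrays was left out, against 0.411 with all of them. Array scaling is argued against as the whole cause, since the median ethanol effect of all genes was at most 0.0753 in size under any scaling, against 0.411 for the list, whose own median stayed at 0.377 or more. A culture difference other than ethanol, such as oxygen, cell density or time since feeding, cannot be told apart from ethanol, because the labels place the arms in no dish or batch; the median of -0.04 in rosettes shows only that no such difference acted on both stages alike. A candidate explanation is therefore an ethanol effect or a difference in oxygen supply, cell density or feeding in the NPC cultures with ethanol. None of these is excluded by these arrays. The list did not rise throughout: adjusted over the list alone, 16 members rose and SLC2A1 fell.

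Other differences between the stages are given as values of NPC minus rosettes in log2 units. The stress response list had a median difference of 0.157, the adhesion list of 0.194 and the mitosis list of -0.0815. With an estimated correlation their adjusted p was 0.114, 0.114 and 0.172, so that only the glycolysis list passed of the 4. Without any 1 of 6 arrays (the 4 rosette arrays, NPC array 2 without ethanol and NPC ethanol array 2) the mitosis list had an adjusted p between 0.0543 and 0.215. Secreted or signalling genes that differed were TAC1 (2.24), SFRP4 (1.68), SPP1 (1.43), VEGFA (1.05), WNT7B (-1.54) and LGI1 (-1.31). Transcription factor genes that differed were BHLHE40 (2.07), ZFP42 (1.48), TFAP2C (-0.921), EOMES (-0.749) and ETV5 (-1.23). With the mean of its probe sets BHLHE40 was at 0.752 and did not pass (limma adjusted p = 0.629). Structural, transport and stress genes that differed were the dim SPTBN4 (2.14), LOX (1.31), SLC1A3 (0.807), DDIT4 (0.696) and TAGLN (0.613). The calls of SPTBN4, SLC1A3, DDIT4 and TAGLN depended on single arrays and ended when some of these were left out. So did those of WNT7B, LGI1, BHLHE40, TFAP2C, EOMES and C5orf46. The dim genes C5orf46 and AP1M2 had fitted differences of 2.19 and 1.71, and ANXA2P2, uncertain between copies, had 1.57. No bound was formed for a difference between stages. The values of C5orf46, AP1M2, SPTBN4 and BHLHE40, which were dim in NPC without ethanol, therefore hold the pseudocount and depend on it. Among 3770 probe sets without a gene symbol, which enter no comparison above, 9 passed with ethanol in NPC, 3 higher and 6 lower.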

How the results depend on the processing

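Spike scaling was the one alternative chosen after seeing the data. Counts of genes called between stages stayed within 1.5 times under every alternative, and those with ethanol did not. Over 6843 values of named genes under the alternatives, 6293 counted as unchanged, 538 no longer passed, 12 newly passed and 0 calls reversed. Sign changes were counted only for genes called in the main setting. The 6293 may therefore include uncalled genes that changed sign. Without 1 array, calls ranged from 7644 to 8726 in rosettes against undifferentiated cells, 8489 to 9388 in NPC against undifferentiated cells, 3782 to 5047 between stages, 1 to 18 with ethanol in rosettes, 65 to 204 in NPC, 21 to 114 in the average and 25 to 75 in the difference. The low values fall in fits with fewer arrays: 1 without any rosette array, 65 without NPC ethanol array 2, 21 without rosette ethanol array 1 and 25 without rosette array 1 of the group without ethanol. Lists that passed ranged from 4 to 7 with ethanol in rosettes (4 without rosette array 2 of the group without ethanol), 1 to 4 in NPC (4 without either undifferentiated array), 4 to 5 in the average and 3 to 6 in the difference. The correlation of ethanol effects ranged from -0.0202 without NPC array 1 to 0.0706 without NPC array 2 of the group without ethanol. Single-array ranges of the list medians were 0.396 to 0.51 for glycolysis in NPC, -0.382 to -0.235 for mesenchyme and -0.191 to -0.134 for the stress response in rosettes, all past the threshold.

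With an estimated correlation 6 lists passed between stages, 1 with ethanol in rosettes, 2 in the average and 1 in the difference. For adhesion in the difference and neural crest in rosettes the estimates were -0.0389 and -0.00703, below the preset 0.01. Their camera p still rose, from 0.000585 to 0.0123 and from 0.000278 to 0.0116. A larger correlation is thus argued against as the cause for these lists. The stress response list in rosettes had an estimate of 0.0284, above the preset. Its median of -0.143 then had a camera adjusted p of 0.0608, against 7.29e-06 with the preset. What else raised these values was not tested. The correlation of ethanol effects was -0.00158 with a pseudocount of 1, 0.0606 with one at the array median and 0.08 with a filter at the 75th percentile; the cause was not tested. In NPC, 4 lists passed with the pseudocount at the array median, 2 with the stricter filter, 2 with centring on the array median, 2 with the mean of a gene's probe sets, 6 with each probe set tested and 3 with only the arrays compared. With quantile normalization 5 lists passed in rosettes. Centring left 4 genes in rosettes. The mean of a gene's probe sets, which averages dim probe sets in, gave 4 genes in rosettes, 83 in NPC, 31 in the average, 28 in the difference and 1 list in the difference, and each probe set tested gave 7 lists in the difference. Without a variance trend 1, 67, 27 and 25 genes passed in rosettes, NPC, the average and the difference. With only the arrays compared, which leaves fewer arrays for the spread, 33 passed in rosettes and 73 in NPC. For these changes of scaling, probe set and variance model the cause was not tested.

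Deviations of arrays with the same number hardly correlated across genes (-0.051 to 0.096, the highest between the NPC arms), so the numbers were not used as pairs. A shared replicate effect is not excluded by this. In both NPC arms array 2 had the higher ACTB 3' to 5' ratio (1.628 against 1.435 without ethanol and 1.497 against 1.37 with it). With the replicate block, 8657, 9366 and 5036 genes passed in the stage comparisons, 13, 177, 84 and 56 in the ethanol comparisons in the order above, and 5 lists passed with ethanol in rosettes. Signal over background limits dim genes: 14130 of 19775 symbols could be tested, and bounds replace folds where a group lay below the array median.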

Other observations

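The lists of FGF and ERK feedback genes and of further mesenchymal genes were written after the ethanol results had been seen, as was the first look at the pattern they test. The tests of these lists without ETV4 and without LOX, which had been named as lower before, and the test of the stage difference without the genes first noticed, were chosen after the values of the members were known. The requirement that the RNA quality test exceed its standard error was also added after its value was known.

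The data also hold a change in a list of FGF and ERK signalling genes, called feedback genes here. The list mixes genes that restrain that pathway with other genes read as its output. In NPC with ethanol, 7 of 21 measured members fell and 1 rose, against 10 and 4 adjusted over the list alone (median -0.383). As the list was built around SPRY1, SPRY2, DUSP6 and ETV5, already seen to fall, this shift restates what prompted it. The members below were chosen after their values were seen. The feedback inhibitors SPRY1 (-0.98 ± 0.069, SE), SPRY2 (-0.80 ± 0.081) and SPRED2 (-0.58 ± 0.084) fell, as did the ERK phosphatase DUSP6 (-0.98 ± 0.081) and the cyclin CCND1 (-0.45 ± 0.072), beside ETV4 and ETV5. EGR1, an immediate-early target of the same pathway, rose by 0.43 ± 0.072 (limma adjusted p = 0.0145). In rosettes 0 members passed over all genes with ethanol in limma, where 1200 of all genes had an unadjusted p under 0.05, and 1 fell adjusted over the list alone (list median -0.106, camera adjusted p = 0.00186, and adjusted p = 0.0191 with an estimated correlation). The 4 members called over all genes with a lower ethanol effect in NPC than in rosettes were the same 4 that prompted the list, and IER3 was called with a higher one, against 8 lower and 3 higher adjusted over the list alone. The whole list had a median difference of -0.192 (camera adjusted p = 0.000297, and adjusted p = 0.0177 with an estimated correlation). Without the 4 that prompted it and ETV4, the other 16 had a median difference of -0.0618 (camera adjusted p = 0.907, over the 5 tests of shortened or further lists given here). The stage difference of the list thus rests on the genes that prompted it and ETV4, and is not shown for the other members.

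The stages themselves also differed in these genes. Of the 21, 14 rose and 3 fell from undifferentiated cells to rosettes (median 1.36, camera adjusted p = 7.00e-05), and 2 rose and 13 fell from rosettes to NPC (median -0.466, adjusted p = 7.59e-05). Both calls held with an estimated correlation, with adjusted p = 0.00731 and 0.00746. The further mesenchymal genes rose in 17 of 20 cases in rosettes against undifferentiated cells and fell in 17 of 20 in NPC against rosettes (medians 1.57 and -1.29).

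Lower FGF and ERK signalling in NPC with ethanol is a candidate explanation for the feedback pattern. The 17 feedback genes other than the 4 first noticed (SPRY1, SPRY2, DUSP6 and ETV5) also shifted down, with a median of -0.19 and 11 of 17 lower. Their camera adjusted p over the 5 tests was 0.0099, but they include ETV4, already known to fall. Without ETV4, 10 of 16 were lower, with a median of -0.178 and a camera adjusted p of 0.0478, close to the threshold. These 16 still hold SPRED2 and CCND1, called lower in the same comparison. As the list was written after the ethanol results had been seen, the shortened list is no independent check. The rise of EGR1 goes against the explanation. A single array is argued against, since the median of the whole list stayed at -0.252 or below without any 1 of the 4 NPC arrays. Less FGF in the medium, fewer responding cells or an ethanol effect on the pathway were not tested and stay open.

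The fall of mesenchymal genes with ethanol in rosettes may reflect fewer mesenchymal cells. The 20 further mesenchymal genes had a median of -0.186, with 13 lower, 1 called over all genes and 7 adjusted over the list alone. Their camera adjusted p over the 5 tests was 0.000111, but they include LOX, already known to fall. Without LOX, 12 of 19 were lower, with a median of -0.155 and a camera adjusted p of 0.000808. A single array is argued against, since the first list's median stayed at -0.235 or below without any 1 of the 4 rosette arrays. RNA quality is argued against as the whole cause: within the NPC arms the array with the higher ACTB 3' to 5' ratio differed in the list's median by -0.00236 and 0.0374 (SE of the list mean 0.0493 and 0.0373), against -0.347 with ethanol in rosettes. A lower expression per cell and an ethanol effect stay open.

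The averaged ethanol effect gave 98 genes, and the highest of the other splits of the arrays within each stage gave 71, so the real split ranked 1 of 18. The split with 71 keeps the ethanol arms whole and swaps them in one stage, which is the test of the stage difference, so it is no arbitrary regrouping. The 8 splits that mix the arms in one stage only gave 0 to 24 genes, and the 8 that mix them in both stages gave 0 to 1. With 18 splits no share under 0.05 can be reached.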
